A study of Mus musculus with 16 samples.

How the data were processed

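RNA of 16 mouse kidneys was sequenced, 4 from each combination of FAN or vehicle with ad libitum or time-restricted access to a high-fat diet, 15 days after treatment. Per the labels' protocols, RNA was extracted with TRIzol from frozen kidney powder, and libraries were made with a stranded poly(A) kit. The labels list separate samples and no animal numbers beyond those in the sample and column names. The numbers of the FAN columns are those of the sample titles of their group raised by a constant. The numbers of FAN ad libitum 7 and FAN time-restricted 6 therefore also occur in a title, which need not be the same sample. FAN columns were mapped to their group only and are named by the column number, not the title number, as in FAN ad libitum 6. Vehicle columns match their titles.

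The values used were the raw read counts per Ensembl gene deposited by the authors as 1 table of 52338 genes. Per the submitters' processing notes, FastQC 0.11.5, STAR 2.5.3a, edgeR 3.26.7 and the mm10 build were used, with no statement of what each did. The counting tool and its strand setting are not given, so reads of overlapping or antisense genes may be mixed. Near-identical genes, such as Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Hspa1a and Hspa1b, or the Cyp4a genes, can share reads, and their values are uncertain. The values were whole numbers and column totals differed. The gene coordinates in the table are not those of GRCm38 (2.9% of starts equal GENCODE M21), so printed coordinates were taken from GENCODE M21 on GRCm38 by Ensembl identifier, which 52081 identifiers matched. Symbols came from the table, and 71 genes had none. Replicates were distinct libraries, with a chi-square per gene of at least 18.4 between any 2 of a group.

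Total counts ranged from 12450812 to 33976660. A count of 0 was read as up to 3 counts, or 0.0883 to 0.241 CPM of the raw total per library. This floor was not scaled as the CPM of genes were. Reads carry no molecular identifiers, so this floor covers counting error only.

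Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by group with a minimum count of 10, which left 17731, and libraries were scaled by TMM. All 16 libraries were fitted in a single 4-group quasi-likelihood model with robust dispersion, and adjusted p are Benjamini-Hochberg values of edgeR's two-sided quasi-likelihood test over all genes tested, with a threshold of 0.05. The contrasts were FAN against vehicle under each feeding regimen, time-restricted against ad libitum feeding in FAN and in vehicle mice, the interaction, and FAN against vehicle over both regimens. Standard errors of log2 changes are from this model, and CPM are TMM-scaled. Log2 CPM for lists and scores used a prior count of 2.

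The FAN signature score of a library was the mean, over genes called for FAN over both regimens, of log2 CPM minus the vehicle mean, signed by the FAN change. Feeding groups were compared within FAN and within vehicle by a two-sided exact permutation test over all 70 assignments, whose smallest p is 0.0286. A gene whose 4 libraries of each group do not overlap arises by chance with a share of 2.86%.

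A total of 41 lists with 733 genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of each contrast. Camera with an estimated correlation and fry stood beside it. With an estimated correlation no list passed in any of the 5 contrasts named by feeding or interaction, where camera with the preset correlation called 28, 29, 17, 17 and 16 lists and fry 34, 32, 17, 2 and 7. Members were counted by edgeR over all genes and adjusted over the list alone. The lists covered tubule injury, extracellular matrix, myofibroblast and pericyte, proximal tubule, thick ascending limb, distal convoluted tubule, collecting duct principal cell, intercalated cell, podocyte, endothelial cell, macrophage and dendritic cell, neutrophil, T and NK cell, B and plasma cell, chemokines and cytokines, interferon response, complement, and MHC class II. They also covered proliferation, p53 targets, cell death, fatty acid oxidation, PPAR-alpha and fasting response, mitochondrial respiration, glycolysis, gluconeogenesis, cholesterol synthesis, fatty acid synthesis, circadian clock, glucocorticoid targets, NRF2 targets, the unfolded protein response, heat shock proteins, renal endocrine, folate handling, immediate early genes, adipocyte, adrenal cortex, erythrocyte, mitochondrial transcripts and sex-linked genes. Some genes belong to several lists.

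Genes were named by a rule. For each FAN and feeding contrast it took the 8 largest changes each way among genes past the threshold with a mean of at least 5 CPM and groups that did not overlap, leaving out unnamed models. It added up to 3 members with the smallest p per list that camera called, and a fixed set of injury, matrix, immune, tubule, clock and metabolic genes. For the interaction it took the 8 smallest p on each side. Some genes that the rule took are not reported here. The contrasts, lists, naming rule and the first group of other settings were set before the data were examined.

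The first group of other settings was no filter on low counts, a log2 change of at least 1, relative log expression scaling, DESeq2 1.42.0, limma-voom, voom with sample quality weights, the replicate number as a block, the compared groups alone, a median score, a score on genes with a log2 change of at least 1, camera with an estimated correlation or on weighted voom values, fry, and leaving out each library. Settings chosen after the data were seen were library size scaling, removal of mitochondrial transcripts, thinning to the shallowest library, leaving out the shallowest library of each time-restricted group, removal of a transcript length trend, and sheet blocks as a covariate or alone. A sheet block is a run of adjacent S numbers in the column names: block 1 holds libraries 6 and 7 of FAN ad libitum, 6 of FAN time-restricted and 1 and 2 of both vehicle groups. Block 2 holds the other vehicle libraries, and block 3 the other FAN libraries. Sheet position as a covariate means these blocks. FAN and vehicle are then linked through block 1 only, so a lost call can reflect less information. The labels do not say whether these mark batches. The 25 gene families looked at for other observations were also chosen after the data were seen. Transcript lengths were found for 17715 of the 17731 genes (99.9%).

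The code was tested on simulated counts with 200 changed genes per contrast. At folds of 1.5, 2 and 4, edgeR recovered 25.4%, 70.1% and 100% of changed genes for FAN under ad libitum feeding (16371 genes), 22.4%, 80.6% and 95.5% for feeding in FAN (16361 genes), 28.4%, 77.6% and 95.5% for feeding in vehicle (16315 genes) and 2.99%, 40.3% and 92.4% for the interaction (16345 genes).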

Results

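Kidney RNA was measured in 16 libraries, 4 in each of 4 groups of mice that had received FAN or vehicle and were fed a high-fat diet either ad libitum or time-restricted. The labels do not spell out FAN, and the column names of the count table carry the word folic. Kidneys were taken on day 15. Total counts ranged from 19266923 to 33035197 in FAN ad libitum, 12450812 to 28255417 in FAN time-restricted, 18788303 to 33976660 in vehicle ad libitum and 14124323 to 31699747 in vehicle time-restricted libraries. At these depths a count of 0 in a library allowed up to 0.0883 to 0.241 CPM of its raw total, before TMM scaling. After low counts were removed, 17731 genes were tested.

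The first principal component, with 65.6% of the variance, separated the groups by treatment. It ran from −113.6 to −101 in FAN ad libitum, −57.6 to −18.5 in FAN time-restricted, 57.8 to 81.4 in vehicle ad libitum and 72.9 to 85.1 in vehicle time-restricted libraries. The share of counts on transcripts of the mitochondrial genome was 10.3% ± 3.83 (SD, n = 4) in FAN ad libitum, 24.9% ± 2.4 in FAN time-restricted, 20.3% ± 2.32 in vehicle ad libitum and 19.8% ± 1.35 in vehicle time-restricted samples. Within FAN ad libitum, libraries 6 and 7 had shares of 7.29% and 6.94%, and libraries 10 and 12, which carry later sheet positions (the S numbers of the column names), had shares between 12.1% and 14.8%.

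**Figure D1:**
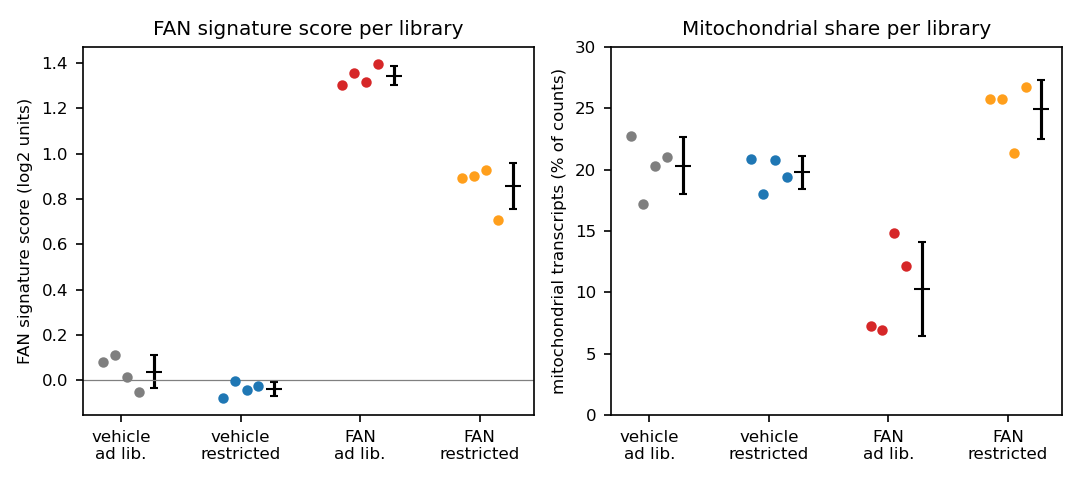
FAN signature score (left, log2) and share of counts on mitochondrial transcripts (right, percent) of each library by group, with points for libraries and group mean ± SD, n = 4. The score averaged 1.34 in FAN ad libitum and 0.857 in FAN time-restricted samples, and the mitochondrial share averaged 10.3% and 24.9%.

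The comparison of FAN with vehicle under ad libitum feeding asked what the treatment had done to the kidney by day 15. Transcripts of tubule injury, matrix and immune cells rose, and those of proximal tubule transport and oxidative metabolism fell. Havcr1, which encodes the tubule injury marker KIM-1 (ENSMUSG00000040405, GRCm38 chromosome 11, 46735080 to 46779578), measured 427 ± 187 CPM (SD, n = 4) after FAN and 5.59 ± 2.14 CPM in vehicle. Its log2 change was 6.26 ± 0.56 (SE, adjusted p = 1.66e-07 by edgeR's quasi-likelihood test). Lcn2, which encodes the injury marker NGAL (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), rose from 11.5 ± 4.75 to 341 ± 39.5 CPM. The adhesion molecule gene Vcam1 (ENSMUSG00000027962, chromosome 3, 116109949 to 116129688) rose from 8.36 ± 3.25 to 278 ± 33.3 CPM. Lrp2, which encodes the endocytic receptor megalin (ENSMUSG00000027070, chromosome 2, 69424340 to 69586065), fell from 1699 ± 167 to 386 ± 112 CPM, and the sodium-phosphate cotransporter gene Slc34a1 (ENSMUSG00000021490, chromosome 13, 55398187 to 55415592) from 2901 ± 246 to 692 ± 375 CPM.

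Among genes averaging at least 5 CPM whose groups did not overlap, which chance gives in 2.86% of splits, the largest log2 rises included Stra6 (7.86), a receptor for retinol-binding protein, the matrix protease gene Mmp7 (7.83) and Fcrls (7.39). They also included Rgs16 (6.95), the latent TGF-beta binding protein gene Ltbp2 (6.85), the dectin-2 gene Clec4n (6.70) and the cytokine gene Lif (6.68). Arhgap36 measured 19.1 ± 3.88 CPM after FAN and 0.0084 ± 0.017 CPM in vehicle, below the counting floor. The largest falls outside the globins were in Hpd (−5.08), an enzyme of tyrosine breakdown, Dnase1 (−5.01), Cyp2d12 (−4.88) and the fatty acid hydroxylase gene Cyp4a12a (−4.84). The globin genes Hba-a1 (−6.19), Hba-a2 (−6.30), Hbb-bs (−4.93) and Hbb-bt (−5.63) fell too, with reads that near-identical copies can share.

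In the tubule injury list 23 of 24 genes rose and 1 did not pass, among them Vcam1 (5.04), the osteopontin gene Spp1 (4.34) and Prom1 (2.46). The list passed limma's camera test (adjusted p = 1.63e-09, and adjusted p = 0.181 with an estimated correlation). In the extracellular matrix list 33 of 34 rose, including fibronectin Fn1 (4.65), the collagen gene Col1a1 (3.72), the cross-linking enzyme gene Loxl2 (3.53), Tgfbi (3.32), Sparc (3.05) and Tgfb1 (2.70), with adjusted p = 0.181 with an estimated correlation. In the myofibroblast and pericyte list 9 of 13 rose, with Thy1 (4.05), Pdgfra (2.57) and Pdgfrb (2.16), and adjusted p = 0.309 with an estimated correlation. The smooth muscle actin gene Acta2 measured 0.53 (adjusted p = 0.155, 0.0227 without vehicle ad libitum 2 and 0.00427 with library size scaling). In the podocyte list 10 of 14 rose and 1 fell, with Synpo (1.86), Thsd7a (1.77) and Plce1 (1.68), and adjusted p = 0.51 with an estimated correlation. The podocyte call was lost with library size scaling (adjusted p = 0.0717), though the median went from 1.04 to 1.75, as the median of all genes rose too.

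Immune transcripts rose. All 24 macrophage and dendritic cell genes rose, including Mrc1 (5.02), Adgre1 (4.58), Ctss (4.36) and Mpeg1 (4.28), as did all 7 neutrophil genes tested, including Mmp8 (3.52), Csf3r (3.39) and Mmp9 (3.37). In the T and NK cell list 19 of 21 rose, with Cd3d (2.53), Ccl5 (2.31) and Lck (1.95). The B and plasma cell list had 2 up, 1 down and 8 not passed and was not called (adjusted p = 0.453). In the chemokine and cytokine list 28 of 32 rose and 1 fell, with Ccl2 (5.43) and Ccl6 (5.07). In the interferon list 24 of 25 rose, with Mx1 (3.07) and Zbp1 (2.91). In the complement list 14 of 15 rose, with C3 (5.42), C3ar1 (4.40) and Cfi (4.31), and in the MHC class II list 8 of 9 rose, with Ciita (2.91) and H2-DMa (2.78). These lists had adjusted p = 0.181 with an estimated correlation, except neutrophil and MHC class II (adjusted p = 0.223 with an estimated correlation) and T and NK cell (adjusted p = 0.241 with an estimated correlation). The neutrophil call was lost with library size scaling (adjusted p = 0.086), where the median went from 3.37 to 4.08.

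Proliferation, p53 target, cell death and immediate early transcripts rose as well. In the proliferation list 26 of 28 rose, with Aurkb (3.90) and Mki67 (3.70). In the p53 target list 12 of 19 rose and 2 fell, with Eda2r (3.63), Pmaip1 (2.94) and the cell cycle inhibitor gene Cdkn1a (2.66). In the cell death list 16 of 24 rose and 4 fell, with the inflammatory caspase genes Casp4 (4.09) and Casp12 (3.65). In the immediate early list 18 of 20 rose, with Atf3 (3.63), Fosl2 (2.65) and Jun (2.51). Each of these 4 lists had adjusted p = 0.181 with an estimated correlation. The p53 call was lost with sheet position as a covariate (adjusted p = 0.0605) and with voom sample weights (0.058).

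Transcripts of tubule transport fell. In the proximal tubule list 35 of 41 genes fell, 1 rose and 5 did not pass, with the brush border enzyme gene Ggt1 (−2.75), Slc6a20b (−2.46), the fatty acid transport gene Slc27a2 (−2.42), Lrp2 (−2.14) and Slc34a1 (−2.07), and adjusted p = 0.181 with an estimated correlation. In the intercalated cell list 11 of 14 fell, with the anion exchanger gene Slc4a1 (−2.07), Atp6v1c2 (−1.75) and Insrr (−1.36), and adjusted p = 0.354 with an estimated correlation. Slc4a1 is also in the erythrocyte list, so its fall cannot be assigned to either cell type. In the collecting duct principal cell list 6 of 11 fell, with Apela (−1.85), Fxyd4 (−1.75) and the aquaporin gene Aqp3 (−1.70), and adjusted p = 0.369 with an estimated correlation. That call was lost without FAN ad libitum 10 (adjusted p = 0.0978) or 12 (0.0802) and without vehicle ad libitum 1 (0.0598), 2 (0.0553) or 4 (0.0704), with sheet position as a covariate (0.09), with voom sample weights (0.103) and with the transcript length trend removed (0.0803). The thick ascending limb list had 1 up, 6 down and 6 not passed (adjusted p = 0.0555). It was called without FAN ad libitum 10 (0.0281) and without vehicle ad libitum 1 (0.0446) or 3 (0.0393), and its median of −0.42 became 0.27 with library size scaling. Within it Egf fell (−1.51) and Umod measured 0.52 (adjusted p = 0.0843, and 0.0101 without FAN ad libitum 12, and 0.000332 with library size scaling).

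Transcripts of respiration, fatty acid oxidation and gluconeogenesis fell. All 33 mitochondrial respiration genes fell, including Suclg1 (−1.80), Idh3g (−1.66) and Uqcrfs1 (−1.61), a subunit of respiratory complex III. In the fatty acid oxidation list 24 of 28 fell, with Ech1 (−1.92), Hadh (−1.72) and Eci2 (−1.40), and in the gluconeogenesis list 11 of 13 fell and 1 rose, with the glucose-6-phosphate transporter gene Slc37a4 (−2.30) and Mdh1 (−1.67). In the NRF2 target list 11 of 17 fell and 1 rose, with Me1 (−2.02) and Gclm (−1.62). Each of these 4 lists had adjusted p = 0.181 with an estimated correlation. All 13 mitochondrial transcripts fell, with mt-Nd2 at −2.18 (adjusted p = 0.26 with an estimated correlation), beside the lower mitochondrial share of these libraries. All 7 erythrocyte genes fell (adjusted p = 0.23 with an estimated correlation). In the heat shock list 8 of 12 fell and 1 rose, with Hsph1 (−1.43) and Hspd1 (−1.33), and adjusted p = 0.47 with an estimated correlation. That call was lost with sheet position as a covariate (adjusted p = 0.0528).

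The median of the cholesterol list was −0.65 (13 of 22 down, 2 up, with Cyp51 at −2.32, and adjusted p = 0.299 with an estimated correlation) and became 0.05 with library size scaling. The median of the fatty acid synthesis list was −0.35 (7 of 19 down, 2 up, with Acss2 at −2.54, and adjusted p = 0.51 with an estimated correlation) and became 0.38. The median of the folate list was −0.28 (9 of 20 down, 5 up, with Ftcd at −3.31, and adjusted p = 0.414 with an estimated correlation) and became 0.42. The fatty acid synthesis call was lost without FAN ad libitum 10 (adjusted p = 0.0777) or 12 (0.0813), and the folate call without FAN ad libitum 10 (0.0625) or 12 (0.0617). With sheet position as a covariate they had adjusted p = 0.106 and 0.0986, and with voom sample weights 0.164 and 0.105. At equal depth the folate list had adjusted p = 0.0553.

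The remaining lists were not called by camera. Counts up, down and not passed were 3, 5 and 4 for distal convoluted tubule, 6, 0 and 12 for endothelial cell, 3, 8 and 8 for PPAR-alpha and fasting response, 6, 4 and 5 for glucocorticoid targets, and 2, 5 and 15 for the unfolded protein response. They were 2, 8 and 3 for renal endocrine, with Kl (−1.39), 0, 1 and 12 for adipocyte, 2, 1 and 1 for adrenal cortex and 1, 1 and 3 for sex-linked genes. Glycolysis had 3 up, 9 down and 5 not passed (adjusted p = 0.0604), and was called without FAN ad libitum 6 (0.0297) or 7 (0.029) or vehicle ad libitum 1 (0.0446). The circadian clock list had 7 up, 10 down and 3 not passed, with Arntl (2.31) up and Dbp (−2.02) and Per2 (−1.02) down, the latter with adjusted p = 0.0951 under library size scaling. Of the fasting genes, Pdk4 rose (1.69). Cpt1a measured −0.62 (adjusted p = 0.00245), with 0.09 under library size scaling and adjusted p = 0.0761 in the earliest sheet positions alone.

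Counts adjusted over the list alone differed for 12 lists: 24 up for tubule injury, 36 down for proximal tubule, 4 up for endothelial cell, 15 up for complement, 9 up for MHC class II and 2 up for gluconeogenesis. They were 11 down for circadian clock, 1 up for the unfolded protein response, 9 down for heat shock, 4 up for renal endocrine and 0 down for adipocyte and for sex-linked genes.

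In all, 10770 genes differed, 5691 up and 5079 down, 6098 of them with a log2 change of at least 1. The earliest sheet positions alone called 9442 genes between 6 and 7 of FAN and 1 and 2 of vehicle. That fit took filter, scaling and spread from all libraries of those positions, the time-restricted ones included. With library size scaling 83.9% of called genes were up against 52.8%, and the median of all genes moved from 0.06 to 0.76, so that changes stand relative to that shift. The median log2 change ran from −0.32 to 0.29 between the shortest and the longest of 5 classes of transcript length. This trend was stronger in FAN ad libitum 6 and 7 than in FAN ad libitum 10 and 12.

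**Figure D2:**
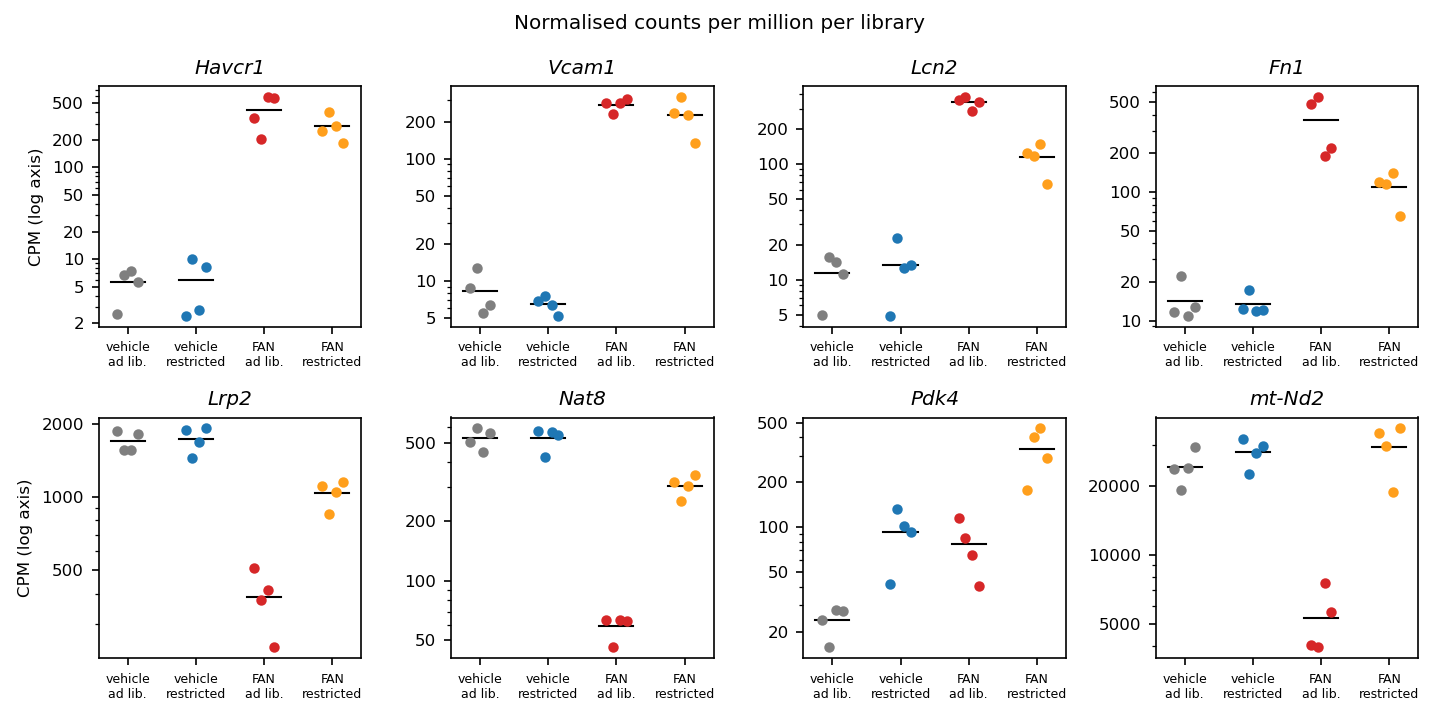
CPM (log axis) of Havcr1, Vcam1, Lcn2, Fn1, Lrp2, Nat8, Pdk4 and mt-Nd2 in each library by group, with points for libraries and a line at the mean, n = 4. Lrp2 averaged 386 CPM in FAN ad libitum and 1039 CPM in FAN time-restricted samples, against 1699 and 1732 CPM in vehicle.

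The comparison of FAN with vehicle under time-restricted feeding asked which of these changes appeared in mice with restricted access to food. Injury, matrix and immune transcripts rose here too. Havcr1 rose from 5.91 ± 3.9 to 280 ± 91.9 CPM (SD, n = 4; log2 change 5.58), Vcam1 from 6.53 ± 1.02 to 230 ± 76.3 CPM (5.12), and fibronectin Fn1 (ENSMUSG00000026193, chromosome 1, 71585520 to 71653200) from 13.4 ± 2.62 to 110 ± 32.1 CPM (3.04). The mannose receptor gene Mrc1 (ENSMUSG00000026712, chromosome 2, 14229392 to 14332057) rose from 2.84 ± 0.314 to 47.7 ± 9.92 CPM (4.07). Lcn2 rose from 13.4 ± 7.34 to 114 ± 34.1 CPM (3.09). Lrp2 fell by 0.74 and Slc34a1 by 1.04 on the log2 scale, with adjusted p = 0.161 and 0.337 once sheet position was a covariate. As that fit links FAN and vehicle through few libraries, it does not tell an effect of sheet position from less information.

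The largest rises by the rule of mean level and separation included Mmp7 (6.44), Stra6 (6.19), the chemokine genes Ccl2 (6.09) and Ccl12 (5.89), the protease inhibitor gene Timp1 (5.97) and Ear2 (5.90). The largest falls outside the globins were in the clock gene Ciart (−3.31), Rnf24 (−2.55), Kcnt1 (−2.55) and Cyp2d12 (−2.68), the last not called with sheet position as a covariate. In the tubule injury list 23 of 24 rose, with the adhesion receptor gene Cd44 (5.24) and Sox4 (2.90), in the extracellular matrix list 31 of 34, with Lox (3.96) and Tgfbi (2.93), and in the macrophage and dendritic cell list 22 of 24, with Ccr2 (5.03) and Ctss (4.40). All 21 T and NK cell genes rose, with Cd3d (3.73) and Trbc2 (3.67), as did all 25 interferon genes, with Gbp2 (2.30), and all 9 MHC class II genes, with H2-Ab1 (3.48). In the complement list 14 of 15 rose, with C3 (4.36) and C3ar1 (4.06), in the proliferation list 22 of 28, with Cenpf (3.34) and Mki67 (3.23), and in the immediate early list 17 of 20, with Atf3 (3.65). Each of these lists had adjusted p = 0.152 with an estimated correlation.

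Proximal tubule transcripts fell, and metabolic ones in part. In the proximal tubule list 26 of 41 fell and 1 rose, with Cubn (−1.26) and Ggt1 (−1.25), and adjusted p = 0.276 with an estimated correlation. In the mitochondrial respiration list 17 of 33 fell, with Mdh2 (−0.95) and Suclg1 (−0.91), and adjusted p = 0.217 with an estimated correlation. In the fatty acid oxidation list 11 of 28 fell, with Ech1 (−0.78) and Eci2 (−0.56), and adjusted p = 0.3 with an estimated correlation. The gluconeogenesis list, with 5 of 13 down and 1 up, was not called (adjusted p = 0.0797, and 0.0334 without vehicle time-restricted 2), nor was the PPAR-alpha and fasting list (median −0.06, adjusted p = 0.433). Of other cell types, the podocyte list had 10 of 14 up (adjusted p = 0.387 with an estimated correlation), the endothelial list 9 of 18 up (0.416), the erythrocyte list all 7 down (0.165) and the collecting duct list 4 of 11 down (0.386). With sheet position as a covariate the endothelial and collecting duct calls were lost (adjusted p = 0.0714 and 0.174). The 13 mitochondrial transcripts had a median of 0.28 (adjusted p = 0.358). Cpt1a measured −0.29 (adjusted p = 0.148), Egf −0.60 (0.186) and Acta2 −0.45 (0.268), and Dbp fell (−2.13). Camera called 17 lists up and 12 down. The thick ascending limb call was lost without FAN time-restricted 11 (adjusted p = 0.148) or vehicle time-restricted 3 (0.0696) or 4 (0.0878), and the NRF2 call without FAN time-restricted 11 (0.0591) or vehicle time-restricted 4 (0.05), and with sheet position as a covariate they had adjusted p = 0.174 and 0.0588. Counts adjusted over the list alone were 32 up for extracellular matrix, 23 up for proliferation and 18 down for mitochondrial respiration.

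In all, 7719 genes differed, 4349 up and 3370 down, and 4974 with sheet position as a covariate. With library size scaling 67.2% of called genes were up against 56.3%. Between the FAN comparisons, which use different vehicle libraries, 3786 genes were up in both against 1395.9 for independent lists, 2932 were down in both against 965.3, and 10 were called in opposite directions. Across genes, which are not independent replicates, the log2 changes had a Pearson r of 0.865.

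**Figure D3:**
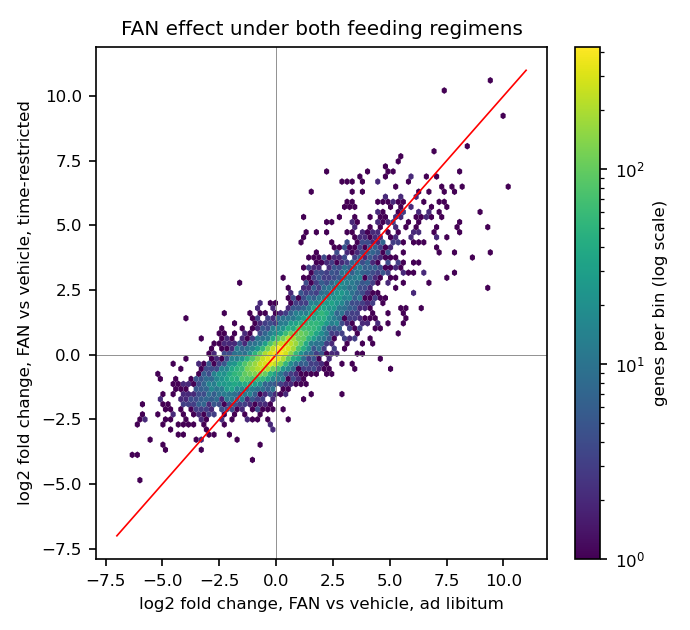
Log2 change of FAN against vehicle under ad libitum feeding (x axis) and under time-restricted feeding (y axis), with the number of genes shown by the colour of each hexagon and a line of equal change. Of 11599 genes called for FAN over both regimens, 8722 had the smaller change under time-restricted feeding.

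The comparison of time-restricted with ad libitum feeding among FAN mice addressed the question in the series title, whether restricted feeding alters kidney damage. Transcripts of proximal tubule and oxidative metabolism were higher under time-restricted feeding, and those of matrix and macrophages lower. Slc27a2 (ENSMUSG00000027359, chromosome 2, 126552407 to 126588243) rose from 1149 ± 207 to 3690 ± 125 CPM (SD, n = 4; log2 change 1.68 ± 0.15 SE, adjusted p = 4.81e-07), against 6149 ± 626 CPM in vehicle ad libitum. Lrp2 rose from 386 ± 112 to 1039 ± 133 CPM (1.43). The matrix gene Fn1 fell from 362 ± 182 to 110 ± 32.1 CPM (−1.71), with −0.93 and adjusted p = 0.0801 among the latest sheet positions alone. The macrophage gene Mrc1 fell from 94.9 ± 12.7 to 47.7 ± 9.92 CPM (−0.99). Havcr1 measured −0.61 (adjusted p = 0.314), Vcam1 −0.27 (0.397) and Ccl2 0.02 (0.976). In the latest sheet positions Havcr1 measured 585.9 and 575.9 CPM under ad libitum and 403, 284.8 and 184.5 CPM under time-restricted feeding. In the earliest it measured 341.8 and 203.1 CPM, and 247.5 CPM in the 1 time-restricted FAN library. Both Havcr1 (−1.22, adjusted p = 0.0259) and Vcam1 (−0.91, adjusted p = 0.00478) were called with library size scaling.

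The largest rises by the same rule included the organic anion transporter genes Slco1a1 (3.17) and Slc22a7 (3.05), Akr1c18 (3.77), Cyp4a12a (3.09) and Dnase1 (2.96). The largest falls included Scube1 (−2.29), the macrophage receptor gene Siglec1 (−1.86) and, with adjusted p = 0.158 and 0.11 in the latest sheet positions alone, the collagen genes Col12a1 (−2.20) and Col15a1 (−2.01). In the proximal tubule list 35 of 41 rose and 6 did not pass, with Slc22a30 (2.33), Slc27a2 (1.68) and Slc6a20b (1.61), and adjusted p = 0.16 with an estimated correlation. Slc34a1 rose (1.14), but had adjusted p = 0.15 with library size scaling, and 0.56 on the log2 scale in the earliest sheet positions, which hold 1 time-restricted FAN library. In the gluconeogenesis list 9 of 13 rose, with Slc37a4 (1.65) and Mdh1 (1.25), and adjusted p = 0.16 with an estimated correlation.

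In the mitochondrial respiration list 30 of 33 rose, with Sdhb (1.39), Uqcrfs1 (1.31) and Cyc1 (1.07), and in the fatty acid oxidation list 24 of 28, with Acot12 (2.12), Hadh (1.51) and Eci2 (1.36). Both had adjusted p = 0.147 with an estimated correlation. In the PPAR-alpha and fasting list 17 of 19 rose, with the lipoprotein lipase gene Lpl (2.52) and Vnn1 (2.14), and adjusted p = 0.223 with an estimated correlation. Pdk4, a kinase that inhibits pyruvate dehydrogenase, rose (2.12, and 0.79 in the earliest sheet positions with their 1 time-restricted FAN library). All 13 mitochondrial transcripts rose, with mt-Nd2 (ENSMUSG00000064345, mitochondrial genome, 3914 to 4951) at 2.48, and adjusted p = 0.223 with an estimated correlation, beside the higher mitochondrial share of these libraries. In the NRF2 list, whose median of 0.52 became −0.13 with library size scaling, 8 of 17 rose and 1 fell, with Me1 (1.74) and Gclm (1.15), and adjusted p = 0.223 with an estimated correlation. That call was lost with voom sample weights (adjusted p = 0.0583).

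In the extracellular matrix list 26 of 34 fell, with adjusted p = 0.521 with an estimated correlation. In the macrophage and dendritic cell list 17 of 24 fell, with Gpnmb (−2.40) and Cx3cr1 (−0.97), and adjusted p = 0.535 with an estimated correlation. In the myofibroblast list 8 of 13 fell, with Thy1 (−1.39), and in the complement list 9 of 15, each with adjusted p = 0.565 with an estimated correlation. In the chemokine list 9 of 32 fell, with Cx3cl1 (−1.01), and adjusted p = 0.581 with an estimated correlation. In the tubule injury list 4 of 24 fell, with adjusted p = 0.58 with an estimated correlation, and Lcn2 fell (−1.58). The interferon call was lost without FAN time-restricted 12 (adjusted p = 0.0524), and the proliferation call without FAN time-restricted 11 (0.0717) or 12 (0.0723). Under library size scaling the adjusted p was 0.0504 for tubule injury, 0.0551 for complement, 0.129 for myofibroblast, 0.146 for proliferation and 0.25 for chemokines. These medians did not shrink: they went from −0.43 to −1.07, −0.63 to −1.26, −0.68 to −1.32, −0.25 to −0.89 and −0.74 to −1.36, as the median of all genes fell too. The erythrocyte list was called up, with 5 of 7 genes and a median of 2.85 (adjusted p = 0.0265, and adjusted p = 0.581 with an estimated correlation). That call was lost without FAN ad libitum 12 (adjusted p = 0.0851) or FAN time-restricted 11 (0.0554), at equal depth (0.0645) and with voom sample weights (0.435). The 21 T and NK cell genes had a median of −0.10 (adjusted p = 0.79). The clock list had 6 up, 2 down and 12 not passed, and Per2 measured 0.26 (adjusted p = 0.237), Arntl −0.60 (0.137) and Dbp 0.18 (0.715). Under library size scaling Per2 measured −0.39 (adjusted p = 0.0395) and Arntl −1.24 (0.00231), and with sheet position as a covariate Dbp measured 0.57 (0.0115). Counts adjusted over the list alone were 36 up for proximal tubule, 31 up for mitochondrial respiration, 30 down for extracellular matrix, 11 down for complement and 3 down for tubule injury.

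In all, 5639 genes differed, 3180 up and 2459 down, and 2129 in the latest sheet positions alone. The earliest sheet positions alone called 4995, but hold 1 time-restricted FAN library, which was assumed to vary like the other groups. The median log2 change ran from 0.28 to −0.18 between the shortest and the longest of the 5 classes of transcript length. Relative to vehicle, the rank correlation of levels with length was 0.253 and 0.245 in FAN ad libitum 6 and 7. It was 0.138 and 0.0917 in FAN ad libitum 10 and 12, and 0.03 to 0.117 in FAN time-restricted libraries. With voom sample weights 9304 genes were called, and with library size scaling 11502, of which 8.61% were up against 56.4% and the median of all genes was −0.67 against −0.02. Of the 5639 genes called with TMM scaling, 4546 also differed between FAN and vehicle over both regimens. Of these, 4432 (97.5%) moved against the FAN change, 1824 of them genes raised and 2608 genes lowered by FAN. With library size scaling 990 genes rose in all, so these counts hold for TMM scaling only.

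The comparison of FAN with vehicle over both regimens called 11599 genes, 6177 up and 5422 down, whose selection did not depend on feeding. With library size scaling 78% of called genes were up against 53.3%. The mean signed log2 change of these genes in each library, a FAN signature score, was 1.34 ± 0.041 (SD, n = 4) in FAN ad libitum and 0.857 ± 0.101 in FAN time-restricted samples, a difference of −0.49 (exact permutation p = 0.0286, two-sided, the smallest that 70 assignments allow). The difference was −0.44 within the earliest sheet positions, where 1 time-restricted library stood against 2, and −0.51 within the latest (exact permutation p = 0.333 and 0.1). In vehicle it was −0.08 (exact permutation p = 0.143), and −0.10 (exact permutation p = 0.0286) without vehicle ad libitum 4. Among FAN mice the score of the raised genes differed by −0.42 and that of the lowered genes by −0.56 (exact permutation p = 0.0286 each). With library size scaling these were −1.05 (exact permutation p = 0.0286) and 0.06 (exact permutation p = 0.4), and the raised genes changed by −0.99 relative to the lowered ones, against −0.98 with TMM. The slope of the FAN change under time-restricted feeding on that under ad libitum feeding was 0.686 across these genes.

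**Figure D4:**
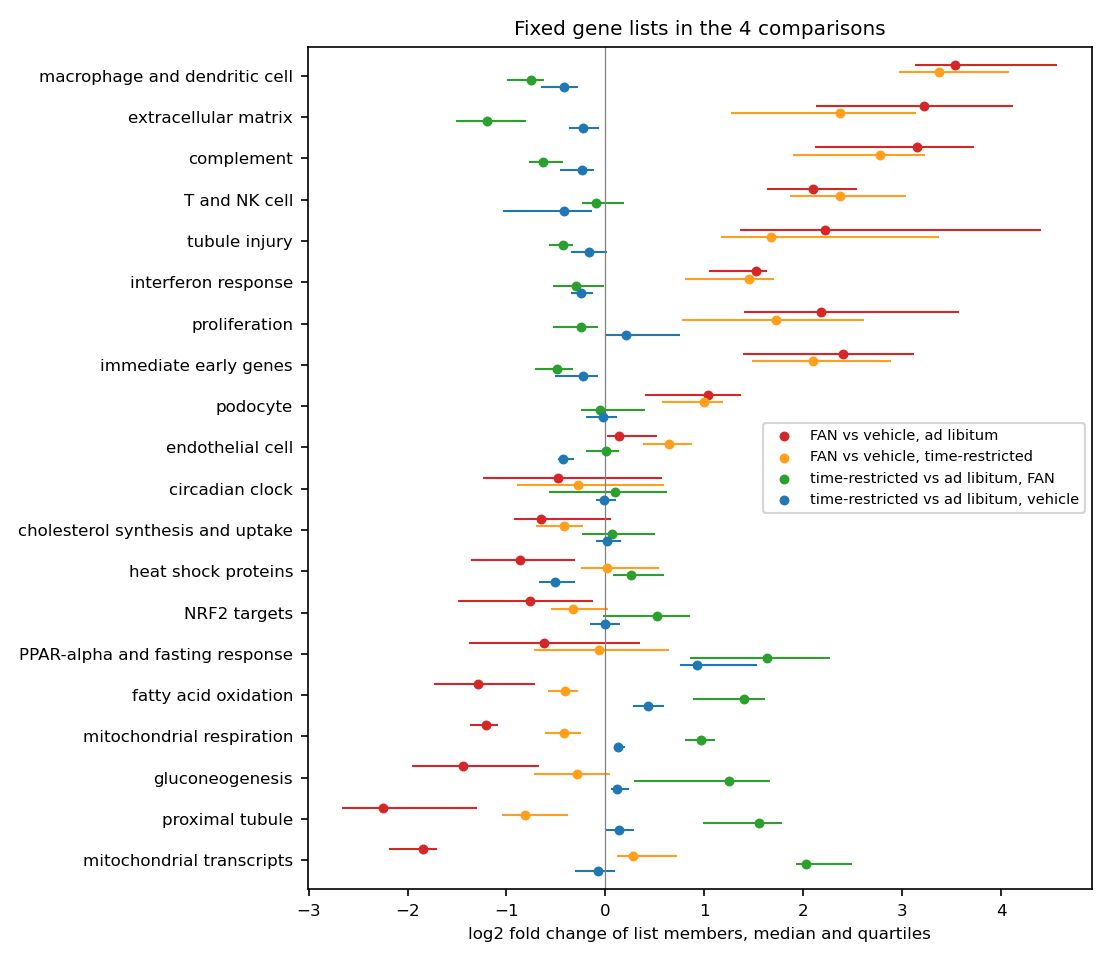
Median log2 change of 20 gene lists in 4 comparisons, with points for medians and lines for the quartiles of each list's genes. The proximal tubule median was −2.25 for FAN under ad libitum feeding, −0.81 for FAN under time-restricted feeding and 1.55 for feeding among FAN mice.

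The interaction asked whether the FAN change differed between feeding regimens. With TMM scaling, metabolic genes that FAN lowered fell less under time-restricted feeding, and a smaller set of matrix genes rose less. With library size scaling negative interactions were the larger set, 6127 against 504 positive ones. Acy1, an aminoacylase gene (ENSMUSG00000023262, chromosome 9, 106432981 to 106438319), measured 25.6 ± 3.52 CPM in FAN ad libitum and 102.6 ± 11 CPM in FAN time-restricted samples (SD, n = 4), against 309 ± 26.9 and 292 ± 19.8 CPM in vehicle. Its log2 interaction was 2.08 ± 0.17 (SE, adjusted p = 3.24e-06). Nat8, an acetyltransferase gene of mercapturate formation (ENSMUSG00000030004, chromosome 6, 85830388 to 85832082), measured 59 ± 8.59 and 303.7 ± 36.9 CPM after FAN, against 526 ± 61.3 and 529 ± 71.8 CPM in vehicle (2.36). The other smallest p on the positive side were in Etnppl (2.65), the enoyl-CoA isomerase gene Eci3 (2.09), Hsd3b3 (2.03), Ttc36 (1.95), Cmbl (1.94) and Sugct (1.92). On the negative side were Hmcn1 (−2.42), Tmem132a (−1.90), the collagen gene Col5a2 (−1.80), Pxdn (−1.22), which cross-links collagen IV, the cell cycle kinase gene Cdk6 (−0.92) and Mapkapk3 (−0.88). Asic3 (−3.92) and Htr2b (−2.99) averaged under 2 CPM in each group.

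In the proximal tubule list 26 of 41 genes had a positive interaction, with a median of 1.31, and in the mitochondrial respiration list 26 of 33, with a median of 0.84. In the fatty acid oxidation list 16 of 28 did, in the gluconeogenesis list 5 of 13, and in the mitochondrial transcripts list all 13. Each of these 5 lists had adjusted p = 0.191 with an estimated correlation. Under library size scaling the medians of the first 4 were 0.69, 0.24, 0.30 and 0.57. In the heat shock list 6 of 12 did, with adjusted p = 0.412 with an estimated correlation, and in the NRF2 list, whose median of 0.41 became −0.18 with library size scaling, 4 of 17 did and 1 was negative, with adjusted p = 0.215 with an estimated correlation. In the extracellular matrix list 5 of 34 had a negative interaction, with adjusted p = 0.589 with an estimated correlation. In the proliferation list 3 of 28 did, with adjusted p = 0.514 with an estimated correlation. The macrophage call, with 2 of 24 genes negative and adjusted p = 0.85 with an estimated correlation, was lost without FAN time-restricted 12 (adjusted p = 0.103) or vehicle ad libitum 3 (0.0555), with library size scaling (0.14, with the median going from −0.44 to −1.02) and with voom sample weights (0.141). The NRF2 call was lost with voom sample weights (adjusted p = 0.0527). Lrp2 had an interaction of 1.40 (adjusted p = 0.00234), Havcr1 of −0.69 (0.575), Slc34a1 of 1.03 (0.113, 0.0242 without FAN ad libitum 6 and 0.0096 with sheet position as a covariate) and Pdk4 of 0.16 (0.894). Counts adjusted over the list alone were 31 for proximal tubule, 30 for mitochondrial respiration, 19 for fatty acid oxidation, 9 for gluconeogenesis, 10 for heat shock, 7 for NRF2 targets and 12 for extracellular matrix.

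In all, 1625 genes had an interaction, 1376 positive and 249 negative. Of 99 other splits drawn, the 3 that regrouped vehicle libraries alone gave more, up to 2706, so the count follows the feeding difference within FAN. The median of all genes ran from 0.35 to −0.15 between the shortest and the longest class of transcript length. With library size scaling 6631 were called, of which 7.6% were positive against 84.7%. With voom sample weights 5264 were called, and 1006 without the shallowest library of each time-restricted group. Of the 1625 genes called with TMM scaling, 1531 also differed between FAN and vehicle over both regimens. Of these, 1520 (99.3%) opposed the FAN change, 1299 of them genes lowered and 221 genes raised by FAN. With library size scaling 504 interactions were positive in all, so these counts hold for TMM scaling only.

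The comparison of time-restricted with ad libitum feeding among vehicle mice asked what feeding did without FAN. No gene passed edgeR's adjusted threshold, with 1143 at an unadjusted p under 0.05 against 886.6 for chance, and DESeq2 called 58 genes, limma-voom 0 and voom with sample weights 35. In simulated counts for this contrast 21 of the 169 genes called by DESeq2 were unchanged ones, against 8 of 142 by edgeR. The PPAR-alpha target Pdk4 (ENSMUSG00000019577, chromosome 6, 5483351 to 5496309) measured 92.2 ± 37.3 CPM under time-restricted and 23.8 ± 5.67 CPM under ad libitum feeding (SD, n = 4; log2 change 1.96, adjusted p = 0.378, and 9.74e-05 by DESeq2). The lipoprotein lipase inhibitor gene Angptl4 (ENSMUSG00000002289, chromosome 17, 33773750 to 33781830) measured 279 ± 51 and 130 ± 26.1 CPM (1.11, adjusted p = 0.194, and 0.000278 by DESeq2). Vnn1 measured 0.95 (adjusted p = 0.127), the carnitine carrier gene Slc25a20 0.62 (0.186), Eci2 0.52 (0.186) and Cpt1a 0.48 (0.562). The chaperone genes Hspa1a and Sdf2l1 measured −1.64 and −1.55 (adjusted p = 0.127 each). Without vehicle ad libitum 1 they had adjusted p = 0.0291 and 0.0389.

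As a group, the 28 fatty acid oxidation genes had a median of 0.44 and the 19 PPAR-alpha and fasting genes one of 0.92. Both passed camera (adjusted p = 7.44e-18 and 1.41e-17, and adjusted p = 0.103 with an estimated correlation for each) and limma's fry (adjusted p = 0.0341 each), which tests whether genes move one way and does not compare them with other genes. Over all genes 0 members passed by edgeR, while 12 and 15 did adjusted over the list alone, all up. Camera also called the unfolded protein response (median −0.32, 5 of 22 down adjusted over the list alone, adjusted p = 0.136 with an estimated correlation), heat shock (−0.51, 5 of 12, adjusted p = 0.281 with an estimated correlation) and MHC class II lists (−0.52, 6 of 9, adjusted p = 0.388 with an estimated correlation). It called the macrophage list down (−0.42, adjusted p = 0.477 with an estimated correlation) and the proximal tubule list up (0.14, adjusted p = 0.654 with an estimated correlation), the latter not without vehicle ad libitum 2 (adjusted p = 0.0584) or vehicle time-restricted 1 (0.136). Of the lists of other cells, camera called erythrocyte up (1.18, adjusted p = 0.285 with an estimated correlation). It called the endothelial (−0.43, adjusted p = 0.425 with an estimated correlation) and neutrophil lists down (−1.01, adjusted p = 0.281 with an estimated correlation). Fry called 2 lists in this comparison, fatty acid oxidation and PPAR-alpha and fasting, and none of the others that camera called. The neutrophil call was lost at equal depth (adjusted p = 0.0871).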

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

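The tests of sheet blocks, scaling and tissue share for the smaller FAN profile, of transcript length, and both tests of red cell transcripts were chosen after the results were seen. The counts over other splits of the libraries and the test of a shared batch were not.

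The FAN change differed between feeding regimens, by the interaction test, for 1625 genes. The log2 interactions were Acy1 2.08, Nat8 2.36, Cmbl 1.94, Hsd3b3 2.03, Sugct 1.92, Etnppl 2.65, Eci3 2.09 and Ttc36 1.95 on the positive side. On the negative side they were Cdk6 −0.92, Pxdn −1.22, Col5a2 −1.80, Hmcn1 −2.42, Tmem132a −1.90, Mapkapk3 −0.88, Asic3 −3.92 and Htr2b −2.99. Among the fixed genes Lrp2 differed by 1.40, and Lcn2 (−1.80, adjusted p = 0.0496 by edgeR) and Fn1 (−1.61, adjusted p = 0.041 by edgeR) were near the threshold. By camera and fry, the median log2 interaction differed for the lists proximal tubule (1.31), gluconeogenesis (1.15), fatty acid oxidation (0.90), heat shock proteins (0.85), mitochondrial respiration (0.84), mitochondrial transcripts (2.12) and NRF2 targets (0.41). With library size scaling these medians were 0.69, 0.57, 0.30, 0.25, 0.24, 1.54 and −0.18 in the same order. With an estimated correlation none passed, with adjusted p = 0.412 for heat shock proteins, 0.215 for NRF2 targets and 0.191 for each of the others.

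A total of 9 values lay far from the other 3 libraries of their group, among 120 groups of values tested, where chance gives about 6. FAN time-restricted 12 had a value of 24.42 on the second principal component (others 39.06 to 41.22) and a signature score of 0.707 (others 0.894 to 0.927). Vehicle time-restricted 2 had 15.1 CPM of Col1a1 (others 7.17 to 8), 17.3 CPM of Fn1 (others 11.8 to 12.4) and 34.8 CPM of C3 (others 10.8 to 13.8). Vehicle ad libitum 2 had 22.1 CPM of Fn1 (others 10.9 to 12.7) and 360 CPM of Kl (others 450 to 459.8). FAN ad libitum 10 had 0.591 CPM of Cd3e (others 1.7 to 1.89) and FAN ad libitum 7 had 6.22 CPM of Arntl (others 7.25 to 7.32).

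Other splits of the same libraries were counted, the real split included. For FAN under ad libitum feeding 1 of 35 splits gave as many genes as the real 10770 (highest other 0). It was also 1 of 35 under time-restricted feeding (7719, highest other 1) and for feeding in FAN (5639, highest other 1054). That is the smallest share that 35 splits allow, which argues against chance without excluding it. For FAN over both regimens 1 of 100 drawn splits gave as many genes (11599, highest other 5171), which argues against chance there too. For the interaction 4 of 100 drawn splits did (1625, highest other 2706). These were the only 4 that kept the feeding groups of FAN, and the 3 that regrouped vehicle libraries alone gave more genes than the real split. The count thus follows the feeding difference within FAN, and chance is not excluded for a contrast with the vehicle libraries. For feeding in vehicle the real count was 0, so all 35 splits gave at least as many by construction (highest other 12) and nothing was tested. For the numbers of lists called, 6 of 35 splits gave as many as 28 for FAN under ad libitum feeding (highest other 32), 2 of 35 as many as 29 under time-restricted feeding (30), 11 of 35 as many as 17 for feeding in FAN (25), 5 of 35 as many as 17 in vehicle (21) and 35 of 100 as many as 16 for the interaction (26). Chance cannot be excluded for these 5 counts of lists.

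The FAN profile was smaller under time-restricted feeding, with a score difference of −0.49. The sheet blocks as the whole cause are argued against by differences of −0.44 within block 1, which holds 1 time-restricted FAN library, and −0.51 within block 3. An even dilution of all other cell types by more proximal tubule would have left the extracellular matrix mean unchanged relative to the T and NK cell mean. That difference changed by −1.06 (exact permutation p = 0.0286), for lists picked after their changes were seen. The value argues against an even dilution only, and uneven changes in cell shares were not tested. A scaling factor moves raised and lowered genes of a library alike, so by construction no choice of scaling moves the gap between them. That gap differed between feeding groups by −0.99 with library size scaling (exact permutation p = 0.0286). Scaling may account for the genes lowered by FAN taken alone, whose change was then 0.0598 (exact permutation p = 0.4). An effect of feeding on the FAN response, which the design names, stays open as a hypothesis.

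The FAN ad libitum libraries parted by sheet block, 6 and 7 from 10 and 12, with 3123 genes called between them. A transcript length trend as the whole cause is argued against, since the blocks still parted on the second component computed anew once the trend was removed. The gap was then 37.8 against 44.5 before (85%), on components that need not be the same axis. A batch shared by all libraries of a block cannot be told apart from a difference between those animals: the block change in FAN time-restricted libraries correlated with it at −0.097 across genes (highest of the other pairs 0.121), but block 1 holds only 1 of those libraries. The design names no biological difference between these libraries, so none was tested.

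Red cell transcripts were lower after FAN. Reads shared between near-identical globin genes are argued against, since the summed alpha globin counts and the summed beta globin counts both fell. On the log2 scale the smaller of these changes was −4.02 and the larger −4.72 (permutation p = 0.00121, the larger of the p values of these sums). A smaller share of blood in the FAN samples may remain: it predicts that red cell genes fall alike, and Alas2 changed by 1.02 relative to Hbb-bs (permutation p = 0.0889), which decides neither way. An effect of FAN on red cells was not tested and stays open.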

How the results depend on the processing

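The alternatives by library size scaling, mitochondrial transcripts, thinning, the shallowest libraries, transcript length and sheet blocks were chosen after the data were seen, and the others were planned. Counts of genes called for FAN stayed within 1.5 times under the other planned and added settings, apart from a log2 threshold of 1, which by its construction left 6098 under ad libitum feeding, 3390 under time-restricted feeding and 4927 over both regimens, and sheet blocks as a covariate, which left 4974 under time-restricted feeding. For feeding in FAN the counts were 1858 with that threshold, 9304 with voom sample weights, 11502 with library size scaling and 2129 in block 3 alone. For the interaction they were 881 with that threshold, 5264 with voom sample weights, 6631 with library size scaling and 1006 without the shallowest library of each time-restricted group. For feeding in vehicle they were 58 by DESeq2, 6 without a filter, 35 with voom sample weights, 1 with the 2 groups alone, 1 with sheet blocks as a covariate, 2 with the length trend removed and 9 in block 2 alone. Except where fewer genes or libraries were used, the cause was not tested.

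Leaving out each library gave 10176 to 10751 genes for FAN under ad libitum feeding, 6693 to 7657 under time-restricted feeding, 4196 to 6314 for feeding in FAN, 0 to 2 for feeding in vehicle (2 without vehicle ad libitum 1, 1 without vehicle time-restricted 3), 1160 to 2371 for the interaction and 11266 to 11662 over both regimens. The score difference in FAN ranged from −0.52 to −0.43 (exact permutation p = 0.0286 in each), and that in vehicle from −0.10 to −0.047, passing only without vehicle ad libitum 4 (−0.10, exact permutation p = 0.0286). The score difference in FAN was −0.44 in block 1, with 1 time-restricted library against 2 (exact permutation p = 0.333), and −0.51 in block 3 (exact permutation p = 0.1), where fewer libraries allow no smaller p. It was −0.48 at equal depth, −0.46 with the length trend removed and −0.77 with library size scaling, where the score took the 12533 genes called for FAN with that scaling.

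The replicate number as a block gave 3400 genes for feeding in FAN, 877 for the interaction, 0 for feeding in vehicle and a score difference of −0.51 in FAN (exact permutation p = 0.25, the smallest that 3 pairs allow). The numbers do not pair the samples: same-numbered libraries correlated at −0.25 to −0.053 in FAN and −0.15 to 0.18 in vehicle, and 3 of 14 libraries correlated best with their number's partner. No paired analysis was possible because FAN and vehicle columns share no numbers, for FAN against vehicle under either regimen or over both.

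The number of lists called was 0 with an estimated correlation in each of the 5 contrasts. Fry called 2 for feeding in vehicle and 7 for the interaction, and camera on weighted voom values 8 for the interaction. Leaving out each library gave 25 to 29, 27 to 29, 14 to 18, 12 to 23 and 10 to 17 lists, the lowest for the interaction without FAN ad libitum 12 or FAN time-restricted 12 (10 each). Cpt1a for FAN under ad libitum feeding turned to 0.087 with library size scaling. Of other values for named genes, 6752 kept the call, or its absence, under the planned settings, 145 lost the call and 53 gained it. Under the added settings these were 3010, 127 and 32. Direction was checked only for genes called in the main fit, so others can change sign unseen in these counts. Calls lost in block 1 for contrasts with time-restricted FAN rest on 1 library of that group and say nothing about stability. For lists the values kept, lost and gained were 2627, 224 and 60, and 966, 42 and 12. Direction of a list was that of camera, so a median that changed sign was not counted. In simulated counts with these depths and numbers of libraries a fold of 1.5 was recovered for 2.99% of genes in the interaction and 28.4% for feeding in vehicle.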

Other observations

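A total of 25 gene families were looked at after the data were seen, and 9 of them are described here. Of all genes tested, 60.7% were called for FAN under ad libitum feeding, 43.5% under time-restricted feeding and 31.8% for feeding in FAN. Among 77 mitochondrial ribosomal protein genes, which build the ribosome inside mitochondria, 73 fell after FAN under ad libitum feeding (adjusted p = 8.72e-08 by fry, median −0.96, and −0.27 with library size scaling) and 41 under time-restricted feeding (adjusted p = 0.000863 by fry). Time-restricted feeding raised 68 of them in FAN mice (adjusted p = 1.41e-05 by fry), with a median of 0.68 that was 0.04 with library size scaling, and 33 had a positive interaction (adjusted p = 0.001 by fry), whose median turned to −0.0016 with that scaling. Among 24 solute carriers of the organic ion family Slc22, 20 fell after FAN under ad libitum and 17 under time-restricted feeding, and 16 rose with time-restricted feeding in FAN mice (median 1.55, and 0.89 with library size scaling). Among 49 cytochrome P450 genes, 28 fell and 9 rose after FAN under ad libitum feeding (median −1.52, and −0.84 with library size scaling), 15 fell and 9 rose under time-restricted feeding, and 23 rose with time-restricted feeding in FAN mice (median 0.77, and 0.14 with library size scaling). Among 17 peroxins, which build peroxisomes, 15 fell after FAN under ad libitum feeding (median −0.97, and −0.28 with library size scaling) and 12 rose with time-restricted feeding in FAN mice, where the median of 0.52 turned to −0.13 with library size scaling.

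Among 30 integrins 20 rose after FAN under ad libitum and 19 under time-restricted feeding, and 14 fell with time-restricted feeding in FAN mice (adjusted p = 0.000418 by fry). Among 15 ADAMTS proteases 12 and 11 rose, and 7 fell with time-restricted feeding (adjusted p = 0.00842 by fry). Among 32 interleukin receptors 23 and 20 rose, and 12 fell with time-restricted feeding (adjusted p = 0.0016 by fry). Among 23 C-type lectins 16 and 17 rose, and 3 fell with time-restricted feeding (adjusted p = 0.168 by fry). The interaction did not pass for these families, with adjusted p by fry of 0.119 for integrins and 0.0626 for ADAMTS proteases. It was 0.0683 for interleukin receptors and 0.623 for C-type lectins. Among 21 vacuolar ATPase subunits, which acidify vesicles and urine, 14 fell after FAN under ad libitum feeding (median above 0, at 0.09, with library size scaling), and 15 rose with time-restricted feeding in FAN mice (−0.07 with that scaling).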
